A study of Mus musculus with 4 samples.

How the data were processed

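ChIP-seq libraries of mouse R1 embryonic stem cells (129SV) were analysed: Input, control IgG, LSD1 and H3K4me2, with 1 library each. Per the labels' protocols, cells were fixed with formaldehyde, chromatin was sonicated, fragments of about 200 bp were selected from the finished libraries on a gel, and 36-base reads were sequenced on an Illumina Genome Analyzer II. Reads were placed on mm9, per the submitters' processing notes. The aligner, its filters, the peak caller, its threshold and the control used for calling are not given in the sources used here. For each library the authors deposited aligned reads as 1 line per read with its strand. No start and strand occurred more than once within a library, so copies had been collapsed before deposit. For IgG, LSD1 and H3K4me2 they also deposited a peak list, with positions but no score, height or p-value. Each list belongs to 1 library.

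Reads were counted as lines of the deposited files, once per start and strand. The start of each read was moved 100 bp along its strand, towards the middle of a fragment, and counted in the region that held it. Pairs of starts on opposite strands of chromosome 19 were counted at distances of 40 to 400 bp. They were most frequent at 70 bp in IgG and LSD1 and at 110 bp in Input and H3K4me2. The LSD1 maximum was shallow, with 3239 pairs at 70 bp and 3212 at 110 bp. Library size was the number of reads, from 3801082 in Input to 6416657 in H3K4me2, and values are reads per 1000000 reads of the library (RPM). Shares carry exact Clopper-Pearson 95% intervals. Ratios of RPM between libraries carry exact binomial 95% intervals conditional on the sum of both counts. Ratios of medians and of gaps to flanks carry bootstrap intervals over 1000 resamples of peaks or gaps. All these intervals cover counting or sampling of regions within 1 library, not differences between cultures. Ratios at single peaks used a pseudocount of 0.5 reads for ranking and for medians. A ratio against a library with no read in a region was computed against a floor of 3 reads in that library. No test between groups was made, since each group held 1 library, and single-peak intervals were not adjusted for the number of peaks.

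Peaks were compared by overlap of at least 1 bp. The LSD1 peaks and the IgG peaks were each placed at random 1000 times, keeping widths and chromosomes and using places with Input reads. Domains joined H3K4me2 peaks within 1 kb, and gaps were stretches of 100 to 600 bp between H3K4me2 peaks with 300 bp of peak on either side. The correlation of LSD1 and H3K4me2 was computed over bins of 10 kb, beside 20 simulations of libraries without enrichment against the same controls. Chromosome lengths were taken as the span with reads. The single-peak ratio was tested on simulated data with known folds, with the background averaged from IgG reads around each peak. In the LSD1 peaks against IgG, over 5106 peaks, the interval lay above 1 for 38% of 50 peaks with a 4-fold change, 90% with an 8-fold change and 0.326% of unchanged peaks. In the H3K4me2 peaks against IgG, over 32256 peaks, these shares were 62%, 98% and 0.696%. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

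The groups and the comparisons of reads in peaks, ratios to IgG, overlaps and reads per chromosome were fixed before the data were examined. So were most processing alternatives for these comparisons. The other alternatives, named in the section on processing, were chosen after seeing the data. The classes of H3K4me2 density, domains, gaps between peaks, central profiles, the spacing of LSD1 peaks, windows of 1 Mb, the spread of LSD1 to H3K4me2 ratios over peaks and the comparison of H3K4me2 peaks on X and autosomes were added afterwards; for the gaps and for a matched comparison of X the predicted outcome was written before the result was seen. The rule for named regions was also fixed before: the 15 LSD1 peaks with the highest ratio to IgG among those with at least 20 LSD1 reads, the 15 H3K4me2 peaks with the most reads, and up to 10 IgG peaks, taken as those with the most IgG reads. The named domains, the widest and those without an LSD1 peak among the 8 widest, were chosen after their values were seen. Positions are in mm9, counted from 1. The gene table at hand is for another assembly, so no region was assigned to a gene, exon or intron. For that reason the 17 gene lists, the always-named genes and the promoter shares fixed beforehand were not run, and the planned correlation over promoters was run on bins, as fixed for that case. No genome sequence was used here, so GC content and repeats were not examined. Alternatives tried were reads without the move of the start, scaling to reads outside peaks, Input as the control, the upper 50% of each list by read density, peaks that touch no IgG peak, peaks with under 100 Input reads, autosomes alone, and other overlap rules, pseudocounts and read minimums.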

Results

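Chromatin of mouse embryonic stem cells was immunoprecipitated with an antibody labelled as against LSD1 and with an antibody against dimethylated lysine 4 of histone H3 (H3K4me2). The recovered DNA was sequenced. The catalogue number in the labels for the LSD1 antibody is known for an H3K27me3 antibody of another supplier, which was not resolved here. The name LSD1 for this library and its peaks therefore follows the label. LSD1 is a demethylase that removes methyl groups from mono- and dimethylated lysine 4 of histone H3, and H3K4me2 is a mark found at promoters and enhancers. The cells were the 129SV line R1, grown with leukaemia inhibitory factor and used at passages 13 to 18. DNA of the same cells without immunoprecipitation (Input) and DNA recovered with control IgG served as the controls of both ChIPs. Each of the 4 groups held 1 library, so no comparison below has a replicate check, no p-value is given, and every difference is one between these libraries. The Input library held 3801082 reads, the IgG library 4755619, the LSD1 library 5833862 and the H3K4me2 library 6416657. Intervals are 95% intervals that cover counting error only. A count of 0 allowed up to 3 reads, or 0.631 reads per 1000000 reads of the library (RPM) in IgG and 0.514 RPM in LSD1.

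The first comparison asked where in the genome the LSD1 library was enriched over its controls. The deposited list for LSD1 held 5106 peaks with a median width of 461 bp, covering 2.60 Mb of mm9. Of the reads of the LSD1 library, 1.94% (exact interval 1.93 to 1.95) lay in these peaks, against 0.436% of IgG reads and 0.136% of Input reads. In RPM the LSD1 library exceeded IgG 4.45-fold (4.38 to 4.51) in these regions and exceeded Input 14.3-fold (13.9 to 14.7). IgG itself exceeded Input there, 3.21-fold (3.12 to 3.31). At single peaks the median count was 19 LSD1 reads against 3 IgG reads, and 419 peaks held no IgG read. In 4577 of the 5106 peaks (89.6%) the interval of the LSD1 to IgG ratio, not adjusted for the number of peaks, lay above 1. The peaks were called on the reads counted here, which raises the LSD1 counts in them.

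The 15 LSD1 peaks with the highest LSD1 to IgG ratio among the 2413 peaks with at least 20 LSD1 reads held between 26 and 40 LSD1 reads each. None of the 15 held an IgG read, so each ratio was computed against a floor of 3 IgG reads in the library. Ranking by this ratio favours peaks without IgG reads. The words "at least" below refer to the floor alone. They cover neither this selection nor the counting error of the LSD1 reads. The first lay on chromosome 15 from 76353110 to 76353782, with 40 LSD1 reads, at least 10.9-fold over IgG, and 62 H3K4me2 reads. On chromosome 10 the region from 9621031 to 9621760 held 38 LSD1 reads and that from 59414748 to 59415488 held 33, at least 10.3-fold and 8.97-fold over IgG. A region of chromosome 8 from 73197805 to 73198501 held 37 LSD1 reads, at least 10.1-fold over IgG. A second region of chromosome 15, from 75771297 to 75772091, held 32 LSD1 reads. Chromosome 19 contributed 3 of the 15, starting at 4097617, 4257123 and 47405110. Of the 15 peaks, 14 lay in an H3K4me2 peak. The exception was the region of chromosome 8 from 128421916 to 128422471, with 26 LSD1 reads and 18 H3K4me2 reads.

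Around the centres of the LSD1 peaks both ChIP libraries rose together. In the central 200 bp the LSD1 library reached 8.64 RPM per kb (8.56 to 8.71) and the H3K4me2 library 9.30 (9.22 to 9.37), against 1.49 for IgG and 0.339 for Input. At 2 to 3 kb from the centre the values were 1.22 for LSD1, 1.75 for H3K4me2, 0.762 for IgG and 0.548 for Input. Input was thus lower at the peak centres than around them, while IgG was higher.

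**Figure D1:**
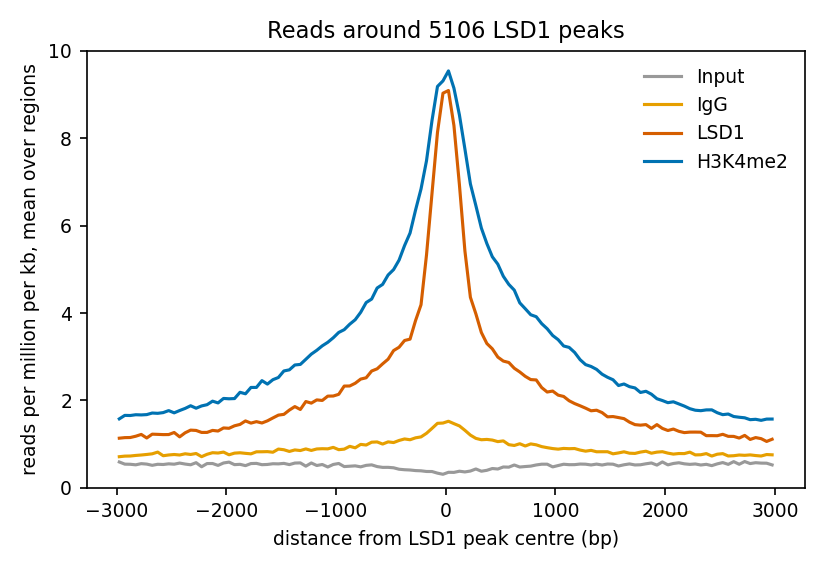
Mean RPM per kb (y axis) of the 4 libraries, as lines, against the distance in bp from the centres of the 5106 LSD1 peaks (x axis). The LSD1 and H3K4me2 lines peak at the centre, at 8.64 and 9.30 over the central 200 bp, while IgG reaches 1.49 and Input falls to 0.339.

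The second comparison asked the same for the histone mark. The H3K4me2 list held 32256 peaks with a median width of 734 bp, covering 27.7 Mb. Of the reads of the H3K4me2 library, 19.9% lay in them, against 10.2% of LSD1 reads, 3.02% of IgG reads and 1.44% of Input reads. The H3K4me2 library exceeded IgG 6.57-fold (6.54 to 6.61) in these peaks and exceeded Input 13.8-fold (13.7 to 13.9). At 31301 of the peaks (97.0%) the interval of the single-peak ratio to IgG lay above 1. These peaks too were called on the reads counted here, which raises the H3K4me2 counts in them. IgG exceeded Input 2.09-fold (2.07 to 2.11) in the same regions.

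Of the 15 H3K4me2 peaks with the most reads, the first 5 held at least 100 Input reads each and were high in every library. They were the region of chromosome 17 from 39979851 to 39985862, 3 regions of chromosome 11 starting at 3030668, 3041358 and 3090863, and the region of chromosome 15 from 74915870 to 74917567. On chromosome 17 the H3K4me2 library was below IgG, at 0.459 of its level (0.431 to 0.489), and so was the LSD1 library, at 0.667 (0.629 to 0.708). The other 10 held fewer than 100 Input reads. Among them, the region of chromosome 14 from 71023658 to 71029327 had an H3K4me2 to IgG ratio of 11.9 (7.42 to 20.4) and an LSD1 to IgG ratio of 6.93 (4.24 to 12.0). In the region of chromosome 4 from 132596690 to 132602387 the ratios were 6.02 (4.31 to 8.63) for H3K4me2 and 3.76 (2.65 to 5.46) for LSD1. The region of chromosome 5 from 111233396 to 111238719 gave 10.7 (6.78 to 17.7) and 5.87 (3.66 to 9.90). The lowest of these 10 ratios were in the region of chromosome 17 from 3081454 to 3083126, at 2.33 (1.83 to 2.98) and 1.76 (1.36 to 2.28), with 39 Input reads. Of the 15 regions, 12 overlapped an LSD1 peak.

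The third comparison paired the library labelled LSD1 with the mark that LSD1 acts on. Of the 5106 LSD1 peaks, 4684 (91.7%, exact interval 90.9 to 92.5) shared at least 1 bp with an H3K4me2 peak. Regions of the same widths placed at random on the same chromosomes overlapped an H3K4me2 peak in a median of 127 cases (range 98 to 164 over 1000 placements). Such placement is a weak comparison for ChIP background, since the 158 peaks of the IgG library exceeded it too (33 against a median of 3). In the LSD1 peaks the H3K4me2 library exceeded IgG 5.22-fold (5.15 to 5.30). In the other direction, 4568 of the 32256 H3K4me2 peaks (14.2%, 13.8 to 14.5) held an LSD1 peak. At the 422 LSD1 peaks outside H3K4me2 peaks the LSD1 to IgG ratio was 3.98 (3.76 to 4.21), and H3K4me2 reads were still above IgG, 2.13-fold (2.01 to 2.27). With only the upper 50% of each list by read density, which shortens both lists, the overlap was 75.5%.

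H3K4me2 peaks with an LSD1 peak were wider than those without, with medians of 1012 and 702 bp (ratio 1.44, bootstrap interval 1.42 to 1.47). Their H3K4me2 density was higher too, with medians of 7.54 and 6.56 RPM per kb (ratio 1.15, 1.14 to 1.16). A wider peak offers more room for an overlap of 1 bp, and width rose with density. Neither contrast was separated from that room. Against IgG the H3K4me2 signal was not higher: the H3K4me2 to IgG ratio was 6.03 (5.96 to 6.10) in peaks with LSD1 and 6.74 (6.70 to 6.79) in those without. Without the peaks that touch an IgG peak these ratios were 6.75 (6.67 to 6.83) and 6.76 (6.71 to 6.80). Against Input it was higher in peaks with LSD1, at 15.9 (15.6 to 16.2) against 13.3 (13.2 to 13.4). IgG itself exceeded Input 2.63-fold (2.57 to 2.69) in peaks with LSD1, so the answer depends on the control. The 27688 H3K4me2 peaks without an LSD1 peak also carried LSD1 reads above IgG, 3.23-fold (3.21 to 3.26), and above Input 6.37-fold (6.31 to 6.43), as IgG exceeded Input 1.97-fold (1.95 to 1.99) there. At the 23612 of them more than 5 kb from any LSD1 peak the LSD1 to IgG ratio was 3.23 as well. Over all H3K4me2 peaks, 17546 (54.4%) had a single-peak LSD1 to IgG interval above 1, several times the number that held a called LSD1 peak.

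When the H3K4me2 peaks were ordered by H3K4me2 density into 10 classes, the share with an LSD1 peak rose at each step, from 4.46% (3.78 to 5.23) in the lowest class to 36.3% (34.6 to 38.0) in the highest. Peak width rose along the same order, from a median of 540 bp to 1030 bp. Per Mb of H3K4me2 peak the number of H3K4me2 peaks with LSD1 still rose, from 76.3 to 300.4. The LSD1 to IgG ratio of reads moved far less. It was 2.94 (2.87 to 3.01) in the lowest class, 3.66 (3.61 to 3.72) in the ninth and 3.32 (3.27 to 3.36) in the highest. The lower value of the highest class rested on peaks that touch an IgG peak, without which it was 3.73 (3.67 to 3.78), against 3.68 (3.62 to 3.74) in the ninth. The H3K4me2 to IgG ratio over all peaks also moved far less than the share. It was 5.47 (5.35 to 5.59) in the lowest class, 7.35 (7.24 to 7.46) in the ninth and 6.74 (6.66 to 6.83) in the highest.

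**Figure D2:**
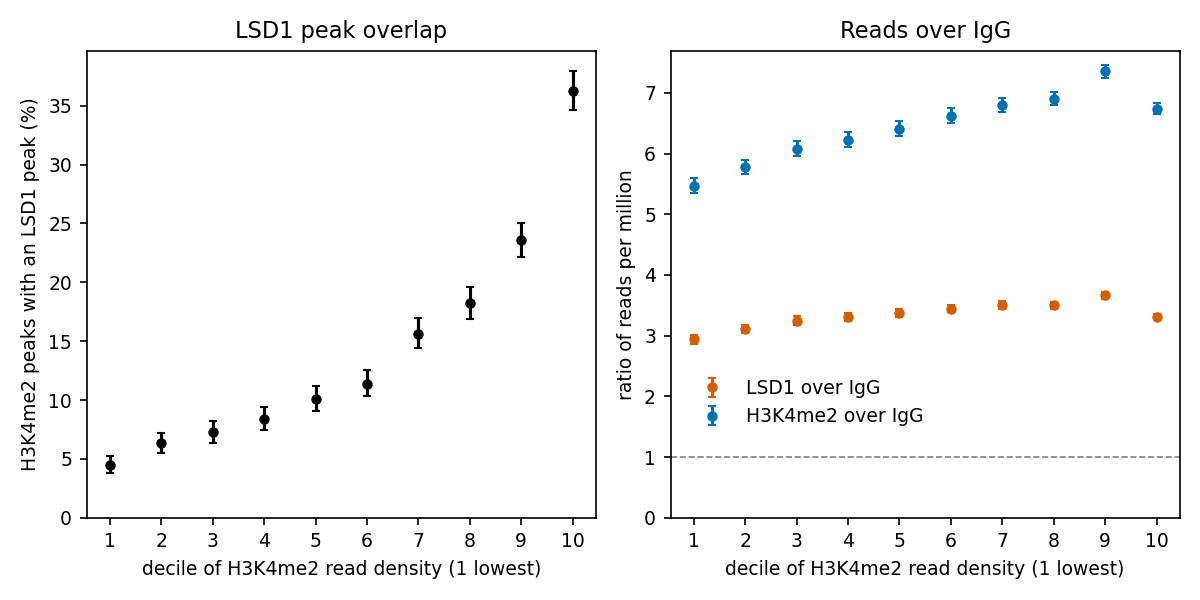
Left, the percentage of H3K4me2 peaks that overlap an LSD1 peak (y axis) in 10 classes of H3K4me2 read density from low to high (x axis); right, the ratio of LSD1 and of H3K4me2 RPM to IgG RPM in the same classes, with a dashed line at 1. Points are class values and bars 95% counting intervals. The share rises from 4.46% to 36.3%, while the LSD1 ratio stays between 2.94 and 3.66 and the H3K4me2 ratio between 5.47 and 7.35.

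H3K4me2 peaks within 1 kb of each other were joined into 23437 domains. The share of domains with an LSD1 peak was 7.80% (7.34 to 8.28) below 1 kb, 23.5% at 1 to 2 kb, 36.7% at 2 to 5 kb 57.6% (52.0 to 63.1) at 5 to 10 kb and 78.3% (56.3 to 92.5) in the 23 domains of 10 kb or more. Wider domains offer more room for a peak. Per Mb of domain the number of LSD1 peaks was 122 below 1 kb, 177 at 1 to 2 kb, 159 at 2 to 5 kb, 142 at 5 to 10 kb and 135 at 10 kb or more, so that it did not rise with width beyond 2 kb. The widest domain, on chromosome 11 from 97516486 to 97534950, spanned 18465 bp and held 6 LSD1 peaks. LSD1 reads exceeded IgG there 4.67-fold (3.70 to 5.95) and H3K4me2 reads 8.17-fold (6.54 to 10.3). Of the 8 widest domains, 2 held no LSD1 peak, on chromosome 15 from 102034445 to 102047233 and on chromosome 14 from 64115835 to 64128503. Their LSD1 to IgG ratios were 2.74 (2.06 to 3.68) and 3.65 (2.74 to 4.95).

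At finer scale, 4585 gaps of 100 to 600 bp (median 277 bp) lay between neighbouring H3K4me2 peaks. H3K4me2 reads per kb in the gaps were 0.345 of those in the 300 bp on either side, in part because the gaps are defined by the absence of an H3K4me2 call. LSD1 reads fell as well, to 0.677 of the flanks, while IgG stood at 0.944 and Input at 0.844. The LSD1 to IgG ratio was 2.38 (2.32 to 2.45) in the gaps and 3.32 (3.26 to 3.38) in the flanks. The gap ratio divided by the flank ratio was 0.717 (0.694 to 0.742, bootstrap over gaps).

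**Figure D3:**
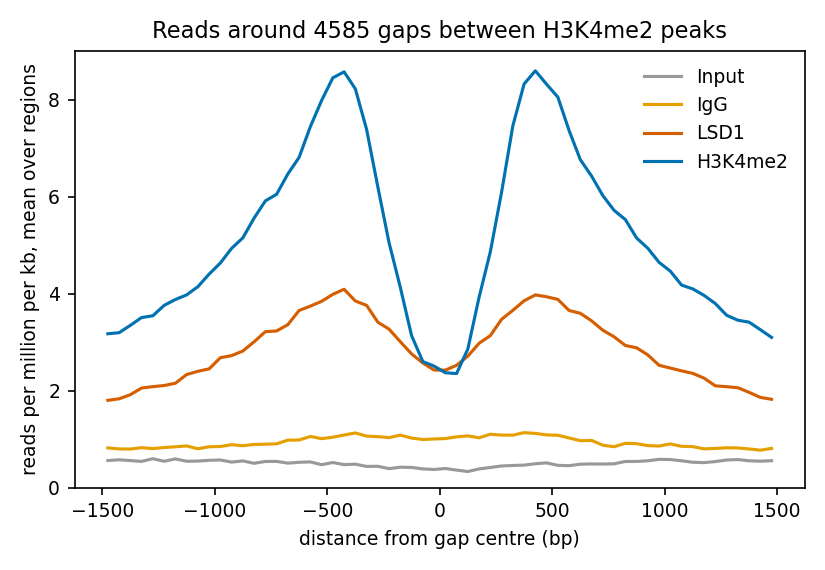
Mean RPM per kb (y axis) of the 4 libraries, as lines, against the distance in bp from the centres of the 4585 gaps between H3K4me2 peaks (x axis). H3K4me2 and LSD1 both dip at the centre, with gap densities of 0.345 and 0.677 of the flanks, while IgG stays nearly level at 0.944.

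Over bins of 10 kb across the genome, the log2 ratios of LSD1 and of H3K4me2 to IgG were correlated with Spearman's rho of 0.633 and Pearson's r of 0.659. Bins are not independent replicates, and the shared IgG library alone gives a correlation. Simulated libraries without enrichment had a rho of 0.532, with a covariance of 0.160 against 0.408 observed. With IgG as the control of LSD1 and Input as that of H3K4me2, so that no control was shared, rho was 0.346 and r was 0.405.

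Among chromosomes, LSD1 peaks were densest on chromosome 11, with 4.72 per Mb, followed by chromosome 19 with 3.50, chromosome 17 with 3.41 and chromosome 7 with 3.32. The median of the 19 autosomes was 2.23 per Mb. H3K4me2 peaks were densest on chromosome 11 too, with 24.5 per Mb against a median of 14.0. Chromosome X held 10 LSD1 peaks, or 0.0611 per Mb, and 247 H3K4me2 peaks, or 1.51 per Mb. Of the H3K4me2 peaks on X, 1.62% (0.443 to 4.09) had an LSD1 peak, against 14.3% (13.9 to 14.6) on the autosomes. Input reads per Mb on X were 0.433 of the median autosome (0.430 to 0.435), whereas the autosomes lay between 0.902 and 1.17. IgG reads per Mb on X were lower, at 0.342 of the median autosome (0.340 to 0.344). In the H3K4me2 peaks of X the LSD1 to IgG ratio was not lower than on the autosomes, at 4.03 (3.60 to 4.51) against 3.38 (3.36 to 3.40), with medians of 6 and 15 LSD1 reads per peak. The H3K4me2 to IgG ratio was higher in the peaks of X, at 10.1 (9.10 to 11.3) against 6.58 (6.54 to 6.61). LSD1 relative to H3K4me2 was thus lower in them, at 0.398 (0.377 to 0.420) against 0.514 (0.513 to 0.516). The peaks were called on these H3K4me2 reads, and X had fewer reads. Neither contrast can therefore be told apart from selection of high H3K4me2 counts in the calling.

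**Figure D4:**
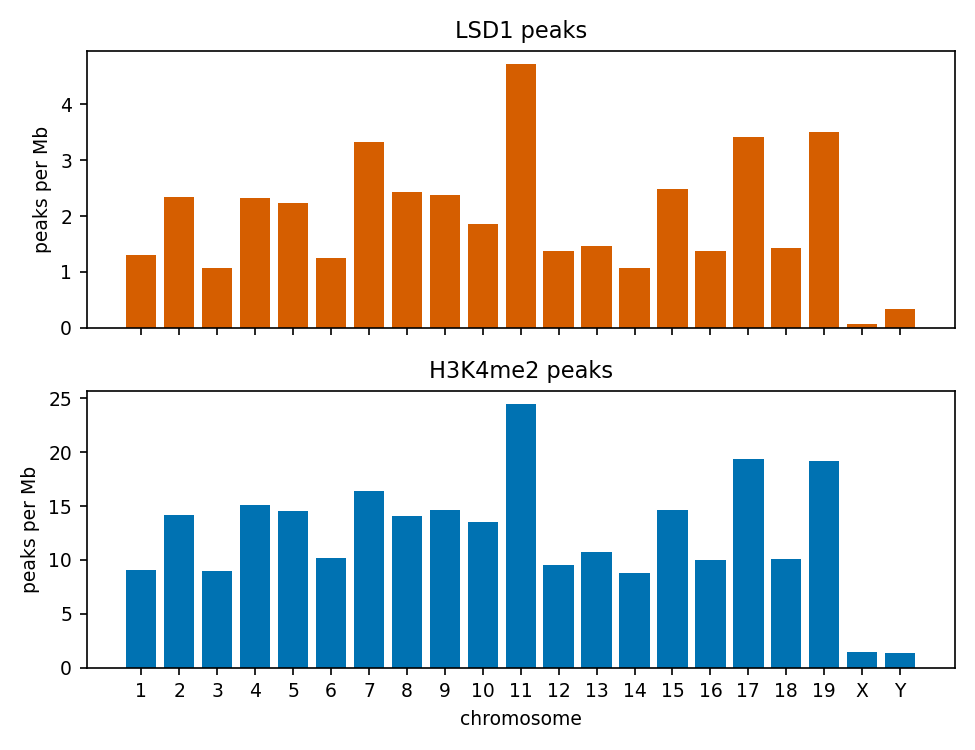
LSD1 peaks (top) and H3K4me2 peaks (bottom) per Mb of chromosome with reads (y axis) for each chromosome (x axis), as bars from 0. Chromosome 11 is highest in both, at 4.72 and 24.5 per Mb, and X is the lowest for LSD1, at 0.0611.

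The control IgG library had a peak list of its own, with 158 short peaks of median width 76.5 bp. They held 0.0704% of IgG reads (0.0680 to 0.0728), 0.0506% of LSD1 reads, 0.0376% of H3K4me2 reads and 0.0197% of Input reads. The 3 IgG peaks on chromosome 17 between 39979941 and 39985779 held 69.9% of the reads in all IgG peaks, and lay in the H3K4me2 peak with the most reads. The others with the most IgG reads included chromosome 11 from 3092978 to 3093926 with 169 reads, chromosome 11 from 108872962 to 108873418 with 138, and chromosome 5 from 51864733 to 51865264 with 124. The last held no Input read, so IgG was at least 33.0-fold over an Input floor of 3 reads. Of all 158 IgG peaks, 41 (25.9%, 19.3 to 33.5) overlapped an LSD1 peak and 33 (20.9%, 14.8 to 28.1) an H3K4me2 peak. Random placement of the IgG peaks gave medians of 0 (range 0 to 3) and 3 (range 0 to 9). Of the 10 IgG peaks with the most reads, 10 overlapped an LSD1 peak and 9 an H3K4me2 peak. In total 36 LSD1 peaks and 21 H3K4me2 peaks touched an IgG peak. In those 36 the LSD1 library was below IgG, at 0.759 of its level (0.728 to 0.791), and in the remaining 5070 LSD1 peaks it was 5.52-fold over IgG (5.43 to 5.62).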

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

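Alternatives for the gap ratio, for H3K4me2 peaks with and without LSD1, for the 2 highest density classes, for their density and for single-peak counts, and the separate controls for bins, were chosen after seeing the data. Over 16 results, 80 alternative values were computed. Of these, 42 stayed within the main value's interval (a count within 1.5 times, a correlation to 2 decimals) and 38 moved beyond it. No ratio or correlation changed direction, while shares and counts had no direction that could change. The order of the 2 highest density classes for LSD1 to IgG did turn, with the highest at 3.73 against 3.68 without IgG peaks and 3.77 against 3.66 with under 100 Input reads. Counting every deposited read line moved nothing by construction, because copies had been collapsed. Its values are among the 42 and say nothing about robustness. No paired analysis was possible because each group held 1 library. Promoter windows and gene lists were not run. With Input as the control, which IgG exceeded in these peaks, the values were 14.3 for LSD1 in LSD1 peaks, 13.8 for H3K4me2 in its peaks, 16.8 for H3K4me2 in LSD1 peaks, 6.37 for LSD1 in H3K4me2 peaks without an LSD1 peak, 0.802 for the gap to flank ratio, and a Spearman correlation over bins of 0.759. The first 3 ratios were, in the same order, 4.81, 7.96 and 6.33 when scaled to reads outside peaks, 3.95, 6.89 and 4.48 in the upper 50% of each list, and 5.52, 6.75 and 6.57 in peaks touching no IgG peak. The share of LSD1 reads in LSD1 peaks was 1.96% with starts not moved, 1.14% in the upper 50% of the list and 1.86% without IgG peaks. For H3K4me2 it was 20.1%, 13.2%, 19.83% and, on autosomes, 19.80%. Overlap of LSD1 peaks with H3K4me2 peaks was 75.5% in the upper 50% of both lists (fewer peaks to meet), 89.5% when 50% of the peak had to be covered and 94.6% within 1 kb. The Spearman correlation over bins was 0.641 on autosomes, 0.644 with a pseudocount of 2, 0.637 with at least 5 control reads and 0.346 with separate controls, which removes the shared IgG noise. A shorter list holds fewer reads by construction, which lowers the shares of reads in peaks. Leaving out the 36 LSD1 peaks that touch an IgG peak, with a ratio of 0.759, raised the LSD1 ratio from 4.45 to 5.52. Scaling to reads outside peaks raises ratios to IgG by arithmetic, since a larger share of ChIP than of IgG reads lay in peaks. The causes of the remaining shifts were not tested. Depth limited single peaks, with a median of 3 IgG reads per LSD1 peak. In the simulation, simulated changes of 2-fold were called in 2% of 50 peaks. Its background was averaged from IgG reads around each peak, so its depth was not exactly that of the peaks.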

Other observations

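All tests in this part were added to the planned comparisons once the data were at hand: for the gap, open chromatin and matched X tests the predicted outcome was written before the result was seen, whereas the spacing of LSD1 peaks, the spread of LSD1 to H3K4me2 ratios, the mixture behind the carry-over value, the thinning of chromosome X, the counts by window, and the reading of both X tests as undecided were chosen only after results were seen. LSD1 peaks lay closer together than random placement gave. Of 5085 pairs of neighbouring LSD1 peaks on a chromosome, 716 had centres within 5 kb of each other, and the median distance was 82.5 kb. Over 100 draws, as many random places with Input reads per chromosome gave a median of 82 such pairs (range 62 to 101). As many H3K4me2 peaks drawn at random per chromosome gave 425.5 (range 377 to 483). The drawn peaks were not matched to the greater width and density of H3K4me2 peaks with an LSD1 peak. The excess over them therefore does not measure clustering of LSD1 beyond that of H3K4me2. The window of chromosome 10 from 80000001 to 81000000 held 37 LSD1 peaks and 136 H3K4me2 peaks, the most LSD1 peaks of the 1283 windows of 1 Mb with any. Its LSD1 to IgG ratio over the whole window was 1.69 (1.63 to 1.75). The window of chromosome 19 from 5000001 to 6000000 followed, with 35 LSD1 peaks and 107 H3K4me2 peaks. Across 31179 H3K4me2 peaks outside IgG peaks with at least 20 reads in both libraries together, the LSD1 to H3K4me2 ratio varied beyond counting with a standard deviation of the natural log ratio of 0.156 (0.117 to 0.201). The same measure for LSD1 against IgG was 0.557, with a wide interval (0.174 to 0.843) that overlaps it. It rested on a smaller set, the 15097 peaks with at least 20 LSD1 and IgG reads together. For IgG against H3K4me2, over 28649 peaks, the measure was 0.634 (0.179 to 0.976).

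The LSD1 library was enriched where H3K4me2 was, and its signal fell where H3K4me2 fell. If the antibody had recovered a histone mark instead of LSD1, the LSD1 to IgG ratio should be lower in the gaps between H3K4me2 peaks than beside them, and it was, at 0.717 of the flanks (0.694 to 0.742). That value goes with such an explanation, but LSD1 bound to nucleosomes that carry its substrate may give the same dip. Carry-over of H3K4me2 material predicts a dip too: a mixture of IgG-like background with 44.7% of H3K4me2-like signal, set in the flanks, gives a gap ratio of 1.57 against 2.38 observed, 1.52 times as much (1.49 to 1.55). Because the gaps were defined by few H3K4me2 reads, that excess may come from their selection, and carry-over cannot be told apart from the others here. The catalogue number in the labels for the LSD1 antibody is known for an H3K27me3 antibody of another supplier, and the gene-list test planned for it was not run.

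H3K4me2 peaks with no called LSD1 peak still carried LSD1 reads. If easier shearing and recovery of open chromatin raised IgG as much as LSD1, the LSD1 to IgG ratio should be close to 1. LSD1 exceeded IgG 3.23-fold (3.21 to 3.26) at these peaks. That goes against such recovery as the whole cause only if it acts equally on both libraries, which was not checked. The ratio is also the excess to be explained, so it is no separate test. IgG exceeded Input 1.97-fold there, so that recovery may account for part of the excess over Input. A candidate explanation is LSD1 binding below the calling threshold, which stays open beside a cross-reacting antibody and carry-over.

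Chromosome X held 10 LSD1 peaks. R1 is a male line, so X is expected in 1 copy per cell, and its Input reads per Mb were 0.433 of the median autosome. At H3K4me2 peaks of X the LSD1 to IgG ratio was 0.582 (0.535 to 0.629) of that at matched autosomal peaks thinned to the Input share of X, a value that the prediction had set against fewer copies; but the match failed, since the H3K4me2 to IgG ratio it should have equalised was itself 0.648 (0.605 to 0.686). Thinning autosomal LSD1 peaks to the LSD1 read share of X (31.2%) gave a median of 41.8 peaks with at least 11 reads (range over 100 thinnings 38.9 to 44.5) against 10 observed, whose counting interval is 4.80 to 18.4, which goes against fewer reads as the whole cause. With at least 20 reads, where counts are low, it gave 2.91 peaks (range 2.17 to 3.46) against 2 observed (0.242 to 7.22). The answer thus depends on the read minimum and on the calling criterion, which is not known here. Thinning was repeated with the most reads in any 200 bp or 300 bp of a peak. At the lowest values of the X peaks it gave 6.16 (range 4.74 to 7.45) and 5.08 (range 3.59 to 6.30). Copy number and depth thus stay open and cannot be told apart here from a lower density of LSD1 sites on X, since the LSD1 read share used for the thinning can itself reflect binding. IgG reads per Mb on X, at 0.342 of the median autosome, were also below the Input value. A share below Input was thus not particular to the LSD1 library.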
